A study of Homo sapiens with 9 samples.

How the data were processed

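Gene expression was measured in MCF7 cells with Affymetrix arrays, 4 of cells stably transfected with pSUPER-mir-125b and 5 of cells with the empty vector, with 1 deposited column per array and no pooling. The deposited values are on the log2 scale, made with RMA by the authors per the submitters' processing notes, which name no version. RMA subtracts background, quantile normalizes the arrays to one another and summarises the probes of each probe set. The medians of the 9 arrays lay between 5.30 and 5.35 and their highest values between 14.32 and 14.36. Quantile normalization forces the arrays to one distribution, so a shift of most transcripts in one direction would not be seen, and array values compress large and dim differences. The array software and the genome build were not given in the sources used here.

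Of 8793 probe sets, 47 were array controls, 7840 were paired with 1 gene symbol by the platform annotation, 388 with several and 518 others with none. Of the 7840, 7838 matched the RefSeq gene table of assembly GRCh38.p14 through their Entrez identifier and took its current symbol, and 2 kept the old one. That table was used for names, chromosomes and the order of neighbouring genes, and no coordinates are printed. The probe set with the highest mean over all 9 arrays stood for each gene, which gave 7713 genes, 122 of them with several probe sets. The 906 non-control probe sets without a single gene were left out of the gene counts. In a limma fit of all non-control probe sets, 59 of these 906 were higher and 63 lower in miR-125b at an adjusted p under 0.05.

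Groups and replicate numbers came from the sample labels. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Each gene was fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with default settings and a group term alone), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A gene "rose" or "fell" where it passed that threshold. Log2 fold changes are miR-125b minus empty vector. Each of 18 gene lists drawn from general knowledge was tested with camera at its preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 18 lists. Their counts are given over all genes and adjusted over the list alone, and 14 genes stood in more than 1 list. Of the lists that passed, luminal genes and hypoxia and glycolysis had estimated correlations (-0.015 and -0.010) below 0.01. Their camera p still rose with the estimate, so that setting changes more than the correlation.

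Genes named by rule were 9 genes of prior interest (ARID3B, ERBB2, ERBB3, TP53, BAK1, ESR1, PGR, MYC and CDKN1A), the 10 with the highest and the 10 with the lowest log2 fold change among changed genes whose groups of arrays did not overlap, and up to 4 members with the smallest p from each list. TP53 was not analysed here. Other changed list members are named as chosen after their values were seen.

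The pipeline was tested on simulated data with the real genes' means and spreads and 200 genes changed by known amounts. It recovered 64% of genes changed by 0.3 on the log2 scale, 90% of those changed by 0.5 and 100% of those changed by 1 or 2, with 5.85% of calls false. With no change it called 0 genes and 0 lists, for genes simulated independently of each other.

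Array quality was read from control probe sets as the 3′ minus 5′ difference of GAPDH and ACTB, the hybridisation spikes and 18S ribosomal RNA, each compared by an exact permutation test over the 126 splits of the arrays. No 2 arrays shared more than 4.79% of their values exactly, so none was counted as a copy. Alternatives were repeated quantile normalization, median centring, leaving out the dimmest 1 in 3 probe sets, an intensity trend with a robust prior, array weights, a replicate block, leaving out each array in turn, averaging a gene's probe sets, testing all probe sets, leaving out possibly cross-hybridising probe sets (names ending in s_at or x_at), stricter thresholds, limma treat against 1.2-fold, and fry for the lists. Added after seeing the data were the GAPDH difference as a covariate, leaving out the array of each group with the lowest spikes, Fisher's exact test of list members, and leaving out chromosomes with unequal directions. Changes of direction along chromosomes were tested with Fisher's exact test over 23 chromosomes and against 10000 random gene orders. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.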

Results

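The samples were MCF7 cells, an established line of estrogen receptor positive luminal breast cancer cells. One population stably carried a pSUPER plasmid with the miR-125b hairpin and the other carried the empty pSUPER plasmid, and both were kept as G418-resistant pools rather than single clones. RNA from 4 miR-125b samples and 5 empty vector samples was hybridised to 9 Affymetrix expression arrays with 8793 probe sets, and the deposited values were RMA expression levels on the log2 scale. The comparison asked which messenger RNAs differed in level between cells stably transfected with the miR-125b plasmid and their vector controls. Mature miR-125b was not measured by these probe sets, so the level of the transfected microRNA was not analysed here. The labels number the replicates without saying that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value given here. Each plasmid is described for a single population, so a difference between the pools cannot be told apart from an effect of miR-125b.

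The cells with miR-125b had far more messenger RNA for ALCAM, an adhesion molecule of the cell surface. They had far less messenger RNA for the membrane protein BST2 (tetherin) and for the amino acid transporter SLC6A14. ALCAM rose 7.16-fold, from 5.76 ± 0.08 (SD, n = 5) in empty vector to 8.60 ± 0.07 (SD, n = 4) in miR-125b on the log2 scale. BST2 was 11.7-fold lower, at 5.15 ± 0.14 (SD, n = 4) against 8.71 ± 0.06 (SD, n = 5). SLC6A14 was 8.21-fold lower, at 3.23 ± 0.21 (SD, n = 4) against 6.26 ± 0.35 (SD, n = 5). The limma test gave adjusted p = 2.18e-12 for ALCAM, 1.53e-12 for BST2 and 5.07e-08 for SLC6A14, and every miR-125b array lay on one side of every empty vector array for each of these genes.

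The 10 genes with the highest log2 fold changes went on with CLIC3, an intracellular chloride channel protein (1.80 ± 0.083, SE), MARCKS, an actin-binding substrate of protein kinase C (1.70), and GSTM3, a glutathione transferase (1.32). CCN2, a matricellular growth factor, rose by 1.25 and WIPF1, a partner of the actin regulator WASP, by 1.12. CYP27B1, the enzyme that makes active vitamin D, rose by 1.07, the paraoxonase PON2 by 1.06, the galectin LGALS3 by 1.05 and the desmosomal protein PERP by 1.01. MARCKS at 2.84 and WIPF1 at 2.89 were dim in the empty vector arrays, below the mean of 4.46 under which 1 in 3 probe sets lay. SLC6A14 was as dim in the miR-125b arrays, so that these 3 fold changes rest on a dim group. WIPF1 was dim in both groups, at 4.01 in miR-125b.

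The genes with the lowest log2 fold changes, after BST2 and SLC6A14, were BEX3 (-1.60 ± 0.072, SE), the dynamin DNM1 (-1.46), QPRT, an enzyme of NAD synthesis (-1.44), and the secreted galectin-binding glycoprotein LGALS3BP (-1.43). AGR2, a disulfide isomerase of secretory cells, fell by 1.23, the zinc finger protein ZNF24 by 1.18, the zinc transporter SLC39A6 by 1.16 and MXRA7 by 1.12. The limma adjusted p of the 20 genes with the highest and lowest log2 fold changes lay between 1.53e-12 and 3.29e-05.

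**Figure D1:**
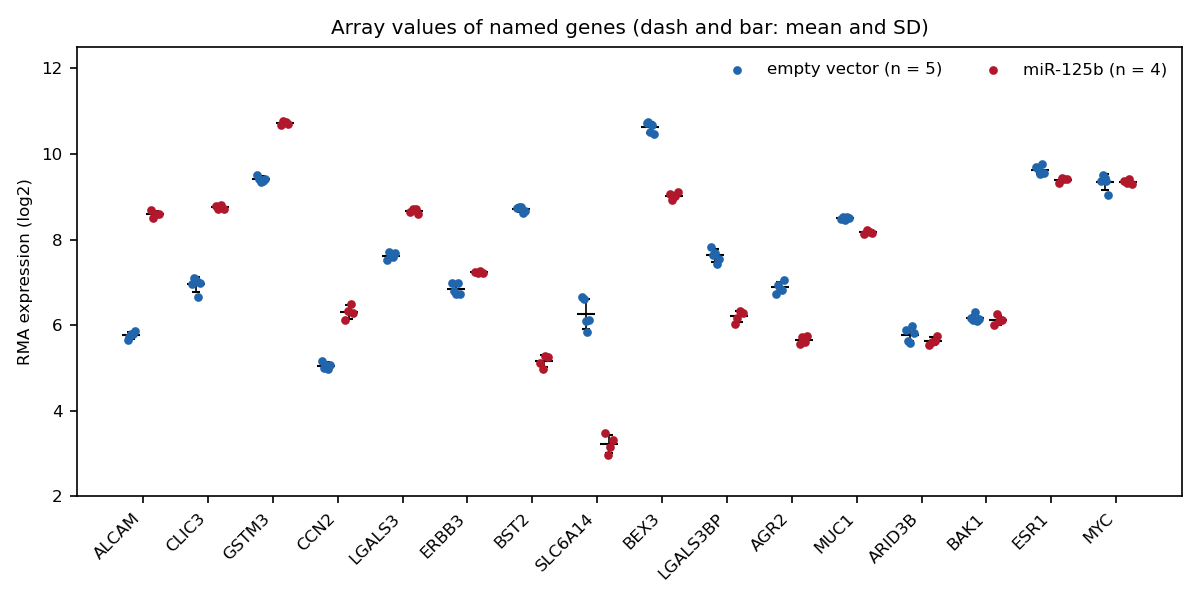
RMA expression (log2, vertical axis) of 16 named genes on each array, with empty vector in blue (n = 5) and miR-125b in red (n = 4), and with the mean as a dash and the SD as a bar. ALCAM stands at 8.60 in miR-125b and 5.76 in empty vector and BST2 at 5.15 and 8.71, while the arrays of ARID3B, BAK1 and MYC overlap between groups.

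Across 7713 genes, 550 rose and 512 fell in miR-125b by limma at an adjusted p under 0.05, and 1877 genes had an unadjusted p under 0.05. Most changes were small: the median absolute log2 fold change of the 1062 changed genes was 0.34, 78.6% of them lay under 0.5, and 10 rose and 14 fell by at least 2-fold. In 921 of the changed genes, and in 1138 of all genes (14.8%), the 2 groups of arrays did not overlap, against 1.59% of genes by chance. Against a 1.2-fold minimum (limma treat), 67 genes rose and 80 fell. With probe sets whose names mark possible cross-hybridisation left out, 263 rose and 277 fell among 4604 genes.

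The empty vector arrays were the more variable, with a median SD per gene of 0.114 (n = 5) against 0.0834 in miR-125b (n = 4). The array's GAPDH control probe sets, which read the 3′ and 5′ parts of that transcript, differed by 2.26 ± 0.045 (SD, n = 4) in miR-125b and by 2.47 ± 0.090 (SD, n = 5) in empty vector. For ACTB that difference was 3.84 ± 0.14 (SD, n = 4) and 4.16 ± 0.20 (SD, n = 5). The exact permutation p, two-sided, was 0.0159 for GAPDH and 0.0318 for ACTB (0.0635 for each after adjustment over 4 measures of array quality), 0.857 for the hybridisation spikes and 0.452 for 18S ribosomal RNA. All 4 miR-125b arrays lay below all 5 empty vector arrays in the GAPDH difference, a measure of RNA quality, so that any difference between the groups of arrays coincided with it. With the GAPDH difference in the fit as a covariate, 96 genes rose and 69 fell.

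The published miR-125b targets did not shift as a list: of 44 measured, 6 rose, 4 fell and 34 did not pass (11 and 5 adjusted over the list alone). Their median log2 fold change was 0.02 (-0.03 with the GAPDH difference as a covariate), and camera gave an adjusted p of 0.504 (adjusted p = 0.611 with an estimated correlation). The receptor ERBB3 rose from 6.85 ± 0.13 (SD, n = 5) to 7.24 ± 0.024 (SD, n = 4), a log2 fold change of 0.39 ± 0.069 (SE) with a limma adjusted p of 0.00189. CBFB, MAP3K11, SGPL1, VDR and PPP1CA also rose, by 0.24 to 0.40. The genes that fell were the mucin MUC1 (-0.33), the semaphorin SEMA4D (-0.33) and the cell death inhibitors BCL2L2 (-0.26) and BCL2 (-0.23). SEMA4D, SGPL1, VDR and PPP1CA are named because they make up these counts, after their values were seen. Among targets that did not pass, ARID3B had a log2 fold change of -0.15 ± 0.081 (SE; limma adjusted p = 0.306), ERBB2 of 0.19 ± 0.069 (0.0886) and BAK1 of -0.05 ± 0.065 (0.712). Without miR-125b replicate 3 the number that fell was 2, and single arrays also ended the calls of BCL2 (without miR-125b replicates 1, 3 or 4, adjusted p up to 0.0805), BCL2L2 (without miR-125b replicates 2 or 3 or empty vector replicate 2, up to 0.0751) and PPP1CA (without any array but empty vector replicates 3 and 5, up to 0.0784).

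**Figure D2:**
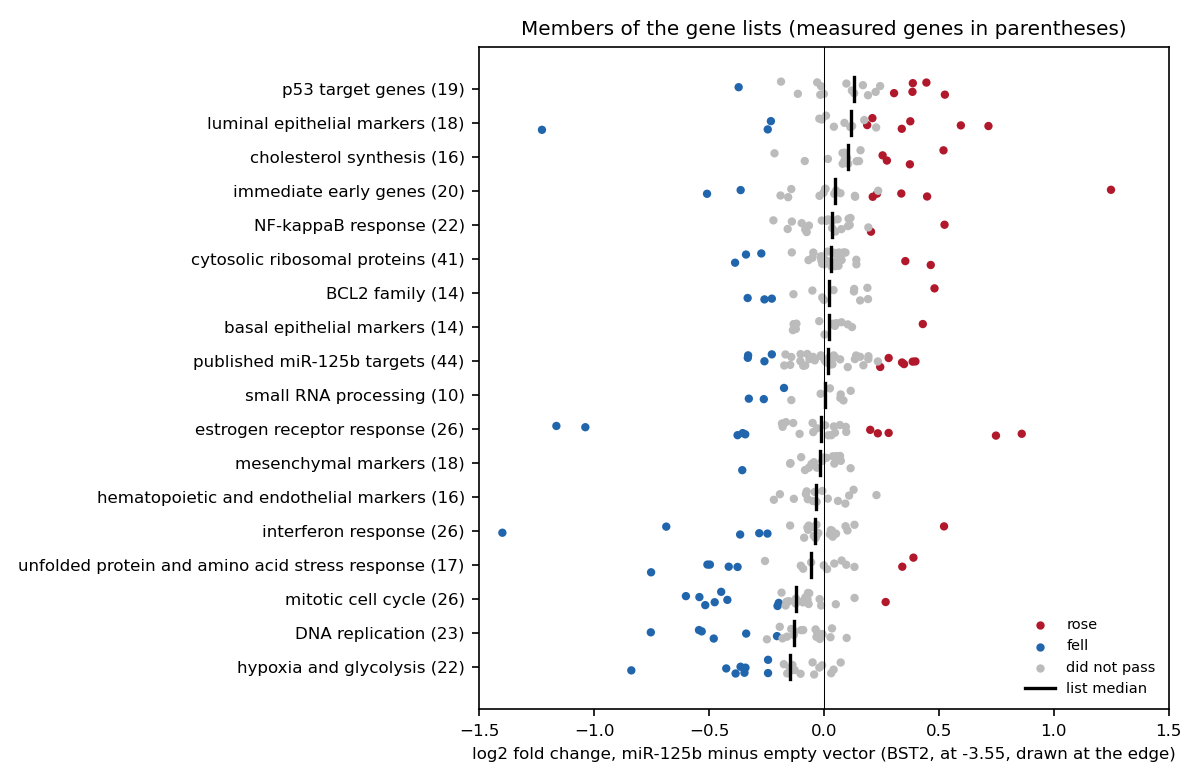
Log2 fold change (miR-125b minus empty vector, horizontal axis) of the measured members of the 18 gene lists, with genes that rose in red, genes that fell in blue, others in grey, the list median as a black line and BST2 (-3.55) drawn at the left edge. The hypoxia and glycolysis list has a median of -0.15 and the p53 target genes one of 0.13, while the published miR-125b targets lie on both sides of 0 (0.02).

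Some genes of cell division fell in miR-125b, on arrays with a mean GAPDH 3′ minus 5′ difference of 2.26 against 2.47 in empty vector. Of 26 measured genes of the mitotic cell cycle, 8 fell, 1 rose and 17 did not pass (9 and 1 adjusted over the list alone). Their median log2 fold change was -0.12 (-0.185 with the GAPDH difference as a covariate). Whether or not they passed, 23 of the 26 lay below 0 and 3 above it. The spindle checkpoint kinase BUB1B fell by 0.60, the midzone protein PRC1 by 0.54, the mitotic kinase AURKB by 0.52 and cyclin CCNB2 by 0.45. The list's shift had an adjusted p of 9.87e-05 by camera and an adjusted p of 0.186 with an estimated correlation. Of the 8 fallen genes 5 (PRC1, BUB1B, CCNB2, NUSAP1 and KIF23) lie on chromosome 15, where 62 genes fell and 8 rose. With the genes of 6 chromosomes of unequal direction left out, a choice made from the changed genes that removes 8 of the list's 9, the camera adjusted p was 0.103 and 1 member fell. The other genes that fell were NEK2 and UBE2C, and the checkpoint kinase TTK rose. NUSAP1, KIF23, NEK2, UBE2C and TTK are named after their values were seen. Without miR-125b replicate 4 the number that fell was 5. Single arrays ended the calls of KIF23 (without miR-125b replicates 3 or 4, adjusted p up to 0.0727), NEK2 (without any array but miR-125b replicate 3 and empty vector replicate 4, up to 0.127), UBE2C (without any but empty vector replicates 2 and 5, up to 0.134) and TTK (without miR-125b replicates 1, 2 or 3 or empty vector replicates 3 or 5, up to 0.0964, which left 0 that rose).

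Of 23 measured DNA replication genes, 6 fell and 0 rose by limma (10 and 0 adjusted over the list alone; 11 lower and 0 higher at an unadjusted p under 0.05), with a median of -0.13. The clamp loader subunit RFC4 fell by 0.75 ± 0.073 (SE), the helicase subunit MCM2 by 0.54, the ribonucleotide reductase subunit RRM2 by 0.53 and the polymerase subunit POLE2 by 0.48, between the same arrays with GAPDH differences of 2.26 and 2.47. CDC45 and TYMS, named after their values were seen, fell by 0.34 and 0.20. The camera adjusted p of the list was 1.92e-05, and the adjusted p was 0.156 with an estimated correlation. RFC4 and MCM2 lie on chromosome 3 and POLE2 on chromosome 14, where most changed genes fell, and with these and 4 other chromosomes left out the adjusted p was 0.000864, with 3 members that fell. TYMS lost its call without any array but empty vector replicates 3 and 5 (adjusted p up to 0.11).

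Of 22 measured genes of glycolysis and the hypoxia response, compared between the same arrays with GAPDH differences of 2.26 and 2.47, 8 fell and 0 rose by limma (12 and 0 adjusted over the list alone; 13 lower and 0 higher at an unadjusted p under 0.05), with a median of -0.15. NDRG1, a gene induced by hypoxia, fell from 8.25 ± 0.09 (SD, n = 5) to 7.41 ± 0.07 (SD, n = 4), the mitophagy receptor BNIP3 by 0.35, the glucose transporter SLC2A1 by 0.34 and pyruvate kinase PKM by 0.36. ADM, PFKFB3, PGK1 and BNIP3L, named after their values were seen, fell by 0.24 to 0.43. The camera adjusted p was 1.92e-05, and the adjusted p was 0.0197 with an estimated correlation, so this was the 1 list of 18 whose call held under both. PKM lies on chromosome 15 and SLC2A1 on chromosome 1, and the 6 others lie on chromosomes whose changed genes were not unequal in direction. Single arrays ended the calls of PGK1 (without miR-125b replicates 1, 2 or 4 or empty vector replicates 3 or 4, adjusted p up to 0.0994) and BNIP3L (without miR-125b replicates 1, 2 or 3 or empty vector replicates 2, 3 or 4, up to 0.136).

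In the list of the unfolded protein and amino acid stress response, 5 of 17 genes fell and 2 rose (6 and 2 adjusted over the list alone), and camera gave an adjusted p of 0.1 (adjusted p = 0.406 with an estimated correlation). The genes that fell included enzymes of serine, glycine and asparagine synthesis, namely PHGDH (-0.75), SHMT2 (-0.41) and ASNS (-0.51), with the chaperone partner SDF2L1 (-0.50) and the secreted hormone STC2 (-0.38). CEBPB, a transcription factor, rose by 0.39 and the chaperone partner DNAJB9 by 0.34. ASNS and DNAJB9 are named after their values were seen, and DNAJB9 lost its call without any array but empty vector replicate 1 (adjusted p up to 0.143), which left 1 that rose.

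Luminal epithelial genes moved both ways, and with the GAPDH difference (2.26 against 2.47) as a covariate the list's adjusted p by camera was 0.0776, with a median log2 fold change of 0.11 in place of 0.12. Of 18 measured, 6 rose and 3 fell (8 and 3 adjusted over the list alone), with a median of 0.12. The keratin KRT7 rose by 0.72, E-cadherin (CDH1) by 0.60 and the tight junction protein CLDN3 by 0.38, and TSPAN1, CLDN4 and SPDEF rose by 0.19 to 0.34. AGR2 fell by 1.23, the estrogen receptor ESR1 from 9.64 ± 0.10 (SD, n = 5) to 9.39 ± 0.05 (SD, n = 4; limma adjusted p = 0.02) and CLDN7 by 0.23. TSPAN1, CLDN4, SPDEF and CLDN7 are named after their values were seen. The camera adjusted p for a rise was 0.0471, and the adjusted p was 0.156 with an estimated correlation. The list's call was also lost without miR-125b replicates 1 (adjusted p = 0.0527), 2 (0.0812) or 4 (0.0743) or empty vector replicates 2 (0.0514), 4 (0.068) or 5 (0.062), and with possibly cross-hybridising probe sets left out its direction turned (0.999). That last setting left out KRT7, CDH1, CLDN3 and SPDEF, which rose, but none of the genes that fell, and 2 members rose in it. The turn is therefore partly built in and does not show that the rise was cross-hybridisation. The list's call was also lost without the 6 chromosomes of unequal direction (adjusted p = 0.106), which hold 3 of its 9 changed genes. Single arrays ended the calls of ESR1 (without miR-125b replicate 1, adjusted p = 0.0727), CLDN7 (without miR-125b replicate 3, 0.0553), TSPAN1 (without miR-125b replicate 4, 0.0639), CLDN4 (without miR-125b replicates 1 or 2 or empty vector replicate 4, up to 0.103) and SPDEF (without miR-125b replicates 2, 3 or 4 or empty vector replicates 2, 3 or 4, up to 0.124).

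Markers of other cell types gave few calls by limma. Of 14 basal epithelial genes 1 rose, the integrin ITGB4 (0.43 ± 0.055, SE), and 0 fell (1 and 0 adjusted over the list alone and at an unadjusted p under 0.05). Of 18 mesenchymal genes 0 rose and 1 fell, the collagen COL1A1 (-0.36 ± 0.10, SE), and 0 passed in either direction adjusted over the list alone. COL1A1 lost its call without miR-125b replicates 1 or 2 or empty vector replicates 1, 2 or 3 (adjusted p up to 0.0943), which left 0 that fell. Of 16 hematopoietic and endothelial genes 0 rose and 0 fell (0 and 0 adjusted over the list alone; 1 higher and 1 lower at an unadjusted p under 0.05), and 1 rose without miR-125b replicate 3. The camera adjusted p of these lists was 0.757, 0.728 and 0.9, and the adjusted p was 0.855, 0.848 and 0.953 with an estimated correlation.

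Estrogen receptor response genes also moved both ways, 5 up and 5 down of 26 measured (5 and 7 adjusted over the list alone; camera adjusted p = 0.407, and adjusted p = 0.681 with an estimated correlation). SLC39A6 fell from 12.16 ± 0.11 (SD, n = 5) to 10.99 ± 0.05 (SD, n = 4) and the lysosomal protease CTSD fell by 1.04, with smaller falls of STC2 (-0.38), SIAH2 (-0.35) and ABCC5 (-0.34). The secreted trefoil peptide TFF3 rose by 0.86 and TPD52L1 by 0.75, and RET, IGFBP4 and MYB rose by 0.20 to 0.28. The progesterone receptor PGR, a classic target of the estrogen receptor, had a log2 fold change of -0.17 ± 0.12 (SE; limma adjusted p = 0.437) at a dim level of 4.22 ± 0.15 (SD, n = 4) against 4.38 ± 0.25 (SD, n = 5). SIAH2, ABCC5, TPD52L1, RET, IGFBP4 and MYB are named after their values were seen. The number that rose was 2 or 3 without any single array but empty vector replicate 3. Single arrays ended the calls of RET (without any but miR-125b replicate 3 and empty vector replicates 2 and 3, adjusted p up to 0.107), IGFBP4 (without any but empty vector replicates 3 and 5, up to 0.127) and MYB (without any but miR-125b replicate 2 and empty vector replicate 1, up to 0.153).

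Of 19 measured p53 target genes, 5 rose and 1 fell (6 and 2 adjusted over the list alone), with a median of 0.13. The stress gene GADD45A rose by 0.53, the phosphatase PPM1D by 0.45, CCNG1 by 0.39 and SESN1, named after its values were seen, by 0.38. The cell cycle inhibitor CDKN1A rose from 8.23 ± 0.12 (SD, n = 5) to 8.54 ± 0.05 (SD, n = 4; limma adjusted p = 0.0073), and TP53I3, an oxidoreductase induced by p53, fell by 0.37. The camera adjusted p was 0.0278 (0.363 with the GAPDH difference, 2.26 against 2.47, as a covariate, when the median was 0.10), and the adjusted p was 0.186 with an estimated correlation. The call was also lost without miR-125b replicate 1 (adjusted p = 0.0698), without empty vector replicate 5 (0.0615) and without the 6 chromosomes of unequal direction (0.342), where 3 of the 6 changed genes lie.

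In the BCL2 family, which governs mitochondrial cell death, 3 of 14 genes fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.757, and adjusted p = 0.844 with an estimated correlation). The death promoter BID fell by 0.33 beside the inhibitors BCL2L2 and BCL2, and the death promoter BIK rose by 0.48. Without miR-125b replicate 3 the number that fell was 1: BCL2 (adjusted p = 0.0805) and BCL2L2 (0.0751) lost their calls. BCL2 lost it also without miR-125b replicates 1 (0.0564) or 4 (0.0671), and BCL2L2 without miR-125b replicate 2 (0.0742) or empty vector replicate 2 (0.0534).

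By limma, 4 of 16 measured cholesterol synthesis genes rose, 12 did not pass and 0 fell (4 and 1 adjusted over the list alone; 7 higher and 1 lower at an unadjusted p under 0.05), between arrays with GAPDH differences of 2.26 and 2.47. The median was 0.10, the camera adjusted p was 0.00379, and the adjusted p was 0.156 with an estimated correlation. Squalene epoxidase (SQLE) rose by 0.52 ± 0.057 (SE), NSDHL by 0.37, HMGCS1 by 0.27 and lanosterol synthase (LSS) by 0.25. LSS lost its call without miR-125b replicate 1 (adjusted p = 0.0506), and 1 gene fell without empty vector replicate 5.

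Of 26 interferon response genes, 5 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.1, and adjusted p = 0.186 with an estimated correlation). BST2 was the first by size, before the ubiquitin conjugase UBE2L6 (-0.69), the membrane protein IFITM1 (-0.37), the proteasome subunit PSMB9 (-0.28) and the transcription factor IRF9 (-0.25), while the RNA sensor RIGI rose by 0.52. The list's mean of -0.18 therefore lay well below its median of -0.04. PSMB9 and IRF9 are named after their values were seen. Without miR-125b replicate 2 the number that fell was 3: PSMB9 (adjusted p = 0.0553) and IRF9 (0.0675) lost their calls. IRF9 lost it also without miR-125b replicate 1 (0.0622) or empty vector replicate 2 (0.0539).

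Of 22 NF-kappaB response genes 2 rose, the inhibitor NFKBIA (0.52 ± 0.053, SE) and IER3 (0.20), and 0 fell by limma (2 and 0 adjusted over the list alone; 3 higher and 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.383, and adjusted p = 0.431 with an estimated correlation). IER3 lost its call, which left 1 that rose, without miR-125b replicates 1, 2 or 4 or empty vector replicates 4 or 5 (adjusted p up to 0.105). Of 20 immediate early genes 5 rose and 2 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.197, and adjusted p = 0.356 with an estimated correlation). CCN2 rose by 1.25, the transcription factors KLF6 by 0.45, FOSB by 0.34 and JUNB by 0.21 and the phosphatase DUSP1 by 0.23, whereas FOS fell by 0.51 and DUSP2 by 0.36. MYC stood at 9.35 ± 0.06 (SD, n = 4) against 9.34 ± 0.18 (SD, n = 5; limma adjusted p = 0.986). JUNB, DUSP1 and DUSP2 are named after their values were seen. Without miR-125b replicate 3 or empty vector replicate 3 the number that rose was 3. JUNB lost its call without miR-125b replicates 1, 2 or 3 or empty vector replicate 3 (adjusted p up to 0.0716) and DUSP1 without miR-125b replicates 3 or 4 or empty vector replicates 3 or 5 (up to 0.1).

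Of 10 small RNA processing genes 3 fell and 0 rose by limma (3 and 0 adjusted over the list alone; 4 lower and 0 higher at an unadjusted p under 0.05). They were TARBP2 (-0.33), a partner of Dicer, GEMIN4 (-0.26) and the helicase DDX17 (-0.17). The list's median was 0.01 and its mean -0.06, of opposite sign, and camera gave an adjusted p of 0.383 (adjusted p = 0.611 with an estimated correlation). Without miR-125b replicates 1, 2 or 4 the number that fell was 1. GEMIN4 lost its call without each of these (adjusted p up to 0.079) and DDX17 without any array but miR-125b replicate 3 and empty vector replicate 1 (up to 0.126). A dimmer DDX17 probe set had a log2 fold change of 0.12 and did not pass.

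Of 41 cytosolic ribosomal protein genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.407, and adjusted p = 0.736 with an estimated correlation). RPS12 rose by 0.46 and RPS21 by 0.35, while RPS7 fell by 0.39, RPS29 by 0.34 and RPLP1, named after its values were seen, by 0.27. Of these 5 genes 4 lie on chromosomes with an unequal split of directions.

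Genes that rose and genes that fell were unevenly spread over the chromosomes. On chromosome 14, 64 genes fell and 6 rose, and on chromosome 15, 62 fell and 8 rose. Chromosome 3 had 45 that fell and 14 that rose, whereas on chromosome 6, 65 rose and 12 fell. Chromosome 1 had 51 that rose and 25 that fell, and chromosome 20 had 33 and 11. These 6 of 23 chromosomes, with 396 of the 1062 changed genes, passed a two-sided Fisher's exact test of direction, at adjusted p from 8.29e-14 (chromosome 14) to 0.023 (chromosome 1). The test treats genes as independent, though neighbouring genes changed together, so these p-values are too small. The weaker splits, as on chromosome 1, are therefore the least certain. The median log2 fold change of all measured genes was -0.11 on chromosome 14 (231 genes) and -0.11 on chromosome 15 (215 genes). On every miR-125b array the mean level of these chromosomes' genes lay below that on every empty vector array. With the 6 chromosomes left out, 360 genes rose and 277 fell by limma. The test cannot see stretches of opposite direction on the same chromosome, as may be so on chromosome 17, where 54 genes rose and 54 fell.

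**Figure D3:**
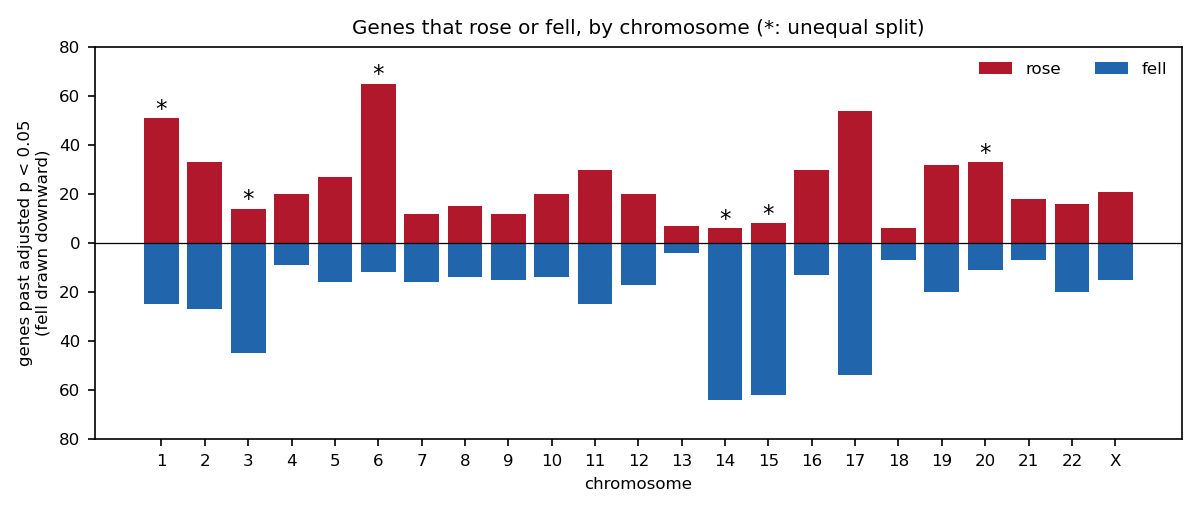
Number of genes past an adjusted p under 0.05 on each chromosome, with genes that rose in miR-125b drawn upward in red, genes that fell drawn downward in blue, and a star over the 6 chromosomes whose split passed Fisher's exact test. Chromosomes 14 and 15 hold 64 and 62 genes that fell, and chromosome 6 holds 65 that rose.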

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

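The outlier test was planned, but part of the genes it was run on were named only after their values were seen. In each group, the gap between the highest or lowest array and its nearest neighbour was set against the group's range by Dixon's test at the 95% level, over 276 groups of values. It passed in 13 of them, and chance passes about 14, so no array is singled out by these passes, of which miR-125b replicate 2 had the most (3).

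Among the published targets, CBFB stood at 7.15 on the log2 scale in miR-125b replicate 3, above 7.02 to 7.03 in the other miR-125b arrays. The collagen COL1A1 stood at 4.75 in miR-125b replicate 2, below 5.18 to 5.25. The p53 target PPM1D stood at 7.45 in miR-125b replicate 1, below 7.63 to 7.66. The estrogen response gene SIAH2 stood at 7.73 in miR-125b replicate 2, below 8.01 to 8.06. The replication gene TYMS stood at 9.03 in miR-125b replicate 4, below 9.11 to 9.12, and the helicase DDX17 at 10.29 in miR-125b replicate 3, above 10.17 to 10.18.

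In the empty vector group, BIK stood at 5.55 in replicate 4, below 5.88 to 5.96 in the other arrays, and CLDN4 at 6.87 in the same replicate, below 6.94 to 6.96. RRM2 stood at 9.85 in replicate 3, below 10.03 to 10.11. GEMIN4 stood at 7.03 in replicate 5, above 6.80 to 6.86, and RPLP1 at 12.66 in the same replicate, above 12.55 to 12.58. The mean of the cholesterol synthesis list, relative to each gene's mean over all arrays, was 0.011 in empty vector replicate 1 and between -0.089 and -0.068 in the other empty vector arrays. The ACTB 3′ minus 5′ difference was 4.04 in miR-125b replicate 2 and 3.75 to 3.80 in the other miR-125b arrays.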

How the results depend on the processing

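The tests with the GAPDH covariate, without the arrays of lowest spikes, without the chromosomes of unequal direction and by Fisher's exact test on list members were chosen only after the results were seen. Over 21 counts and list shifts, 432 of 485 values under an alternative kept their side of the threshold, or a count within 1.5 times. A list that passed in neither fit counted as kept whatever its direction, and 6 of the 18 lists had passed in the main fit. Counts of list members were less stable: 124 of 720 moved by over 1.5 times. The hypoxia and glycolysis list kept its call in all settings run (adjusted p 4.32e-06 to 0.0197). Causes were not tested except where the setting itself leaves fewer genes or samples or asks for a larger change. Of 2217 values for 116 named genes, 1966 kept their call or lack of one, 251 lost a call and 0 reversed; MYC, BAK1 and PGR, which did not pass, changed sign in 9. Dim probe sets may limit what can be called, which was not tested here: 83.2% of changed genes lay above the median level of 5.35.

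By limma, 296 genes rose and 296 fell at an adjusted p under 0.01, 10 and 14 with a 2-fold minimum, 67 and 80 by treat, 263 and 277 without possibly cross-hybridising probe sets, 96 and 69 with the GAPDH covariate, and 360 and 277 without the 6 chromosomes. The covariate raised the standard errors 1.89-fold (median 0.0695 before, 0.131 after). With it, 1 hypoxia and glycolysis gene fell (8 without it), 2 mitotic genes fell (8), 2 replication genes fell (6), and 0 targets rose (6) or fell (4). Replication genes that fell numbered 10 with the intensity trend and robust prior and 3 without possibly cross-hybridising probe sets. Leaving out single arrays gave 400 to 595 that rose and 380 to 504 that fell.

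The luminal list, which had passed, had an adjusted p of 0.0899 with repeated quantile normalization, 0.0525 with median centring, 0.0912 without the dimmest probe sets, 0.0776 with the GAPDH covariate, 0.0828 without the arrays of lowest spikes (miR-125b replicate 4 and empty vector replicate 5), 0.106 without the 6 chromosomes, 0.156 with an estimated correlation and 0.0347 to 0.0812 without single arrays. Its direction reversed without possibly cross-hybridising probe sets (0.999), a setting that left out KRT7, CDH1, CLDN3 and SPDEF but none of its fallen genes. The p53 list had 0.112 without the dimmest probe sets, 0.118 without possibly cross-hybridising ones, 0.363 with the covariate, 0.0562 without the arrays of lowest spikes, 0.342 without the 6 chromosomes, 0.186 with an estimated correlation, 0.0686 by Fisher's exact test and 0.013 to 0.0698 without single arrays. With an estimated correlation the mitotic list had 0.186, DNA replication and cholesterol synthesis 0.156 each, and 1 list passed. These losses need not come from correlation. Without the 6 chromosomes, chosen by the direction of their changed genes, the mitotic list had 0.103 and 3 lists passed. Losses there are partly built in. Cholesterol synthesis had 0.105 by Fisher's exact test.

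Fry, which does not set a list against other genes, passed 11 lists for one direction and 16 for change either way. Its directional test passed 5 lists that camera did not: estrogen response (0.028), interferon (1.58e-05), NF-kappaB (0.0381), unfolded protein and amino acid stress (0.00788) and immediate early genes (0.00324). The interferon list also passed without possibly cross-hybridising probe sets (0.0131), and the unfolded protein and amino acid stress list by Fisher's exact test (0.018).

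The replicate numbers did not pair the arrays one to one: same-numbered arrays correlated in their deviations from the group means at 0.0875, -0.0062, -0.012 and 0.042, and no miR-125b array correlated best with its own number. The second principal component of the arrays (17.1% of the variance) nevertheless fell with the number in both groups. It went from 1.56 to -2.05 in miR-125b and from 12.0 to -8.48 in empty vector. Whether the numbers follow an order shared by both groups was not tested. With the replicate block, without empty vector replicate 5, 457 genes rose and 491 fell, 853 of the 1062 kept their call, and the luminal and p53 lists had an adjusted p of 0.0722 and 0.0584; it changed no other list's call. The planned test of genes with a miR-125b seed site was not run, since no 3′ UTR sequences were used here.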

Other observations

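The tests with the GAPDH covariate were chosen only after the results were seen, and each pattern was tested on the data in which it was noticed.

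Genes that changed in the same direction lay side by side. On chromosome 6, 9 of 10 neighbouring measured genes from ATG5 to SMPD2 rose, among them the surface protein CD24, the transcription factor FOXO3 and the stress gene SESN1, with a median log2 fold change of 0.42. On chromosome 15, 8 of 10 from IDH2 to VPS33B fell, among them the helicase BLM and the mitotic gene PRC1, with a median of -0.47. On chromosome 20, 8 of 10 from ATP5F1E to SLCO4A1 rose, among them the ribosomal gene RPS21, with a median of 0.47. The most seen in 1000 random gene orders was 7 of 10. Stretches with 7 of 10 also lay on chromosomes outside the 6 of unequal direction. On chromosome 17, 7 of 10 fell from ACADVL to CHRNB1 and 7 of 10 rose from P4HB to GPS1. On chromosome 21, 7 of 10 rose from UBE2G2 to LSS. Leaving out the 6 chromosomes may therefore not remove every stretch. All the stretches named here were chosen after their values were seen, for their many changed genes of one direction.

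Fold changes of neighbouring measured genes correlated over 7676 pairs (Spearman 0.166 across genes, which are not independent replicates), above the highest of 10000 random gene orders (0.0475). Cross-hybridisation between related neighbours is argued against as the whole cause, since without such pairs the correlation was 0.152 against a random highest of 0.0798. A regional artefact that varies between the arrays of a group is argued against as the whole cause, since the highest correlation over 10 splits of the empty vector arrays was 0.063, but that value and the median of 0.0275 lie above the central 95% of random orders (up to 0.0219), so that part of the correlation also arises within a group. A candidate explanation, as a hypothesis, is a difference in gene dosage over chromosome stretches between the 2 cell pools, though DNA copy number was not analysed here. Joint regulation of neighbours downstream of the microRNA stays open, as do an artefact shared by all arrays of a group, which would cancel in those splits, and whether the shift of the mitotic list (5 of its 8 fallen genes lie on chromosome 15) follows the stretches.

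The 3′ over 5′ signal of GAPDH was lower on all miR-125b arrays than on all empty vector arrays. The fit with the GAPDH difference as a covariate cannot settle whether RNA quality is the whole cause of the changed genes. Its slope rests on the spread of that difference within each group, since the groups do not overlap in it. In that fit the median log2 fold change of the 1062 genes in their own direction was 0.341 (0.343 without the covariate). Their sign was kept by 1060. Of these genes 157 kept their call, as the median standard error went from 0.0695 to 0.131 because the GAPDH difference and the group share most of their variance (R² = 0.717). For the mitotic, DNA replication and hypoxia lists the median of 71 members was -0.138 without the covariate and -0.159 with it, and 62 of the members lay below 0. RNA quality stays open as a cause, in whole or in part.

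The published miR-125b targets did not fall as a list, although the cells stably carried the miR-125b plasmid. Mature miR-125b was not measured, so its level in these cells is not known here. The targets' median log2 fold change was 0.0185. It turned to -0.0332 with the GAPDH covariate, so that RNA quality stays open as a mask. Dim probe sets could hide a fall: the 28 targets brighter than the median gene had a median log2 fold change of -0.027, at the 15.3rd percentile of random lists of genes as bright (their central 95% lay between -0.062 and 0.077). The camera test in limma of these 28 targets pointed to a rise, which did not pass. Changes over chromosome stretches could also mask one: relative to their 10 nearest measured neighbours, the targets' median was -0.0113, at the 31st percentile of random lists of the same size (their lowest 2.5% lay below -0.0476). Neither can be told apart from an absence of a fall in messenger RNA here, because each median lies within the central 95% of its random lists, and repression of translation alone or an adaptation of stably selected cells was not tested.

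Over 100 of the 126 splits of the 9 arrays into 4 and 5, only the real one gave as many as its 1062 changed genes. The highest other gave 319. As 1 in 100 is the smallest share these splits can give, a chance split of the arrays is unlikely for the gene count but not excluded. For lists, 2 of the 100 splits gave at least 6, the real one and another with 6, a share under 0.05. As 8 of the 99 others gave at least 5, a chance split is unlikely for the lists but not excluded. Neither count bears on chance differences between the cell pools. The other split with 6 lists kept all 4 miR-125b arrays on one side with 1 empty vector array. So did 3 of the 7 splits with 5 lists, and the remaining 4 kept 3 of the miR-125b arrays together. All of these splits share most of the real grouping. The 47 splits with 2 miR-125b arrays on each side gave a median of 0 lists and at most 4, but 19 of them gave at least 1, as did 59 of all 99 other splits, so that a single list passing camera at its preset correlation is common here without the full real grouping.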
